A study of Homo sapiens with 6 samples.

How the data were processed

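RNA was extracted with a column kit from MOLM-13 cells after 24 h with DMSO or 50 nM DEG-35, and 1 mRNA library was made per sample with a SMARTer kit, per the labels' protocols. The 6 libraries form 2 groups of 3, taken from the treatment label of each sample. The submitters' processing notes name the genome build hg19 and the tools STAR, featureCounts and DESeq2, without versions, options or order, so whether reads were counted by strand and how reads of copied or overlapping genes were treated are not given in the sources used here.

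The data are 1 table that the authors deposited. It holds, per the file headers, a log2 fold change, a p-value and an adjusted p-value for each gene. The deposited log2 fold changes run from -4.99 to 6.70, and neither the headers nor the labels say which group is the numerator or whether the values were shrunk. They were read as DEG-35 over DMSO. The authors kept genes with an adjusted p-value below 0.05: no value in the deposited table reaches it, and the largest p-value is 0.0227. For each of the 2789 genes with a p-value above 1e-04, the adjusted p times the rank divided by p lay within 0.1% of 15064, as a Benjamini-Hochberg adjustment over 15064 genes gives. Ranks thus have no gap, and a gene absent from the table either did not pass or was not tested. The table has no counts, mean levels or per-library values, so the depth of each library is unknown, and no interval or floor that needs it is given.

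Because single genes could not be tested anew, the authors' adjusted p-values were used as deposited, which was 1 of 3 plans set for the possible contents of the file before the data were examined. A standard error was computed for each gene as the absolute log2 fold change divided by the normal quantile of its two-sided p-value. It equals the standard error of a Wald test, and that the p-values come from such a test is assumed, not stated. The implied SE has a median of 0.0891 and a maximum of 1.54, and cannot be had for 3 genes with a p-value of 0. Precision differed between directions: of 874 genes with an implied SE above 0.2, 613 (70.1%) were higher.

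The 23 gene lists were fixed before the data were examined. Symbols were matched through the RefSeq gene table of GRCh38.p14: 6269 matched directly, 422 through a synonym and 140 not at all. These counts include 12 symbols that had been turned into dates by a spreadsheet and were not restored. The 12 stayed among the other genes in the list tests and were left out of the largest rises and falls and of the groups by symbol. For the 19 lists with at least 5 listed members, the higher and lower members were compared with the other genes of the table by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. This was the plan for a table holding only genes past a threshold. Tests that need per-library or complete gene statistics (camera, estimated correlations) could not be run. Whether more members of a list were listed than chance gives was tested by a one-sided hypergeometric test among 15064 genes, taking all members as tested, adjusted over the 23 lists and added after the values had been seen.

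The genes named were chosen by a rule fixed before the data were examined. It takes 11 genes of interest (among them the targets, cereblon, related neosubstrates, MYC, CDKN1A and MDM2), the 8 largest rises and 8 largest falls, for each list the up to 3 members with the smallest adjusted p, and the leading member against the list's majority. Some genes that the rule takes are not reported here. The rule's level minimum could not be applied, as the table has no levels. The 8 largest rises and falls among genes with an implied SE of at most 0.2, unlisted members given by name and genes named in the closing section outside this rule were chosen after their values were seen.

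Alternatives fixed beforehand were an adjusted p of 0.01, a minimum absolute log2 fold change of 1, Benjamini-Hochberg and Bonferroni adjustment over the p-values of the table, and lists without members shared between lists. Added later were Bonferroni adjustment over 15064 tests, a maximum implied SE of 0.2 (the 3 genes with a p-value of 0 kept), for lists also the genes above it, the stricter thresholds for lists, exact symbols only, and a shift of all log2 fold changes by 0.3 either way, since the scaling factors are unknown. The shift was added to the listed genes alone, so no gene entered or left the table as it would with other scaling factors. For neighbouring genes and transcript lengths GENCODE release 29 on GRCh38 was used for order, strand and length only. Permutation and matched draws numbered 10000. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Tested on simulated data for the DEG-35 against DMSO table, the method recovered 15000 as the number of tests when 15000 had been simulated, gave implied SEs within 0.0629% of the true ones, and called 8 of 200 random lists at an unadjusted p below 0.05. The simulated p-values were Wald p-values of independent genes. The simulation thus checks the computation alone, not the origin of the deposited p-values or the error rate for lists of co-regulated genes.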

Results

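MOLM-13, an established human acute myeloid leukaemia line with a KMT2A (MLL) fusion, was cultured for 24 h with 50 nM DEG-35 or with the solvent DMSO. The study names DEG-35 as a degrader of IKZF2 (Helios, a zinc-finger transcription factor) and of CK1α, the kinase encoded by CSNK1A1 and a negative regulator of p53. Each group had 3 RNA-seq libraries, and the question was which genes DEG-35 regulates. The values come from 1 table, the authors' deposited comparison of both groups, which lists 6831 genes with an adjusted p below 0.05 and gives a log2 fold change, a p-value and an adjusted p for each. Its header does not say which group is the numerator. All directions below read the values as DEG-35 over DMSO, the usual order, and every one of them would turn round if the order were the other. No per-library values were analysed, so the depth of each library is unknown, and the errors given are standard errors implied by each fold change and its p-value. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values may measure technical spread alone.

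DEG-35 was accompanied by changes in a large part of the transcriptome. Of the 6831 genes in the authors' deposited table, 3218 were higher and 3613 lower with DEG-35, and the adjusted p-values imply that 15064 genes had been tested, so 45.3% passed. Higher genes made up 47.1% of the table, a share that would become 36.6% or 60.8% if all log2 fold changes were shifted down or up by 0.3. Here and below, the shift was applied to the listed genes alone, and no gene entered or left. It therefore does not give the counts that other scaling factors would. Most changes were small: the median absolute log2 fold change was 0.47, and 1251 genes changed by at least 1 on the log2 scale, 637 up and 614 down. Among the degradation targets, IKZF2 mRNA rose, with a log2 fold change of 0.82 ± 0.131 (implied SE) and an adjusted p of 3.71e-09 in the authors' deposited table. CSNK1A1 mRNA rose by 0.18 ± 0.0613 on the same scale in that table (adjusted p = 0.00988). The compound acts on the proteins, so neither value tests the group labels. The authors' deposited table gave lower mRNA for GSPT1, a translation termination factor, at -0.32 ± 0.0618, and for the zinc-finger gene ZFP91 at -0.24 ± 0.0656. CRBN, IKZF1, IKZF3 and MYC were not among the listed genes, which means that they did not pass or were not tested.

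Most of the largest listed rises belonged to imprecisely measured genes. In the authors' deposited table PTCHD4 stood at 6.70 ± 1.25, MYBPHL at 5.50 ± 1.49, LOC101448202 at 5.46 ± 1.49, LOC253573 at 5.18 ± 1.54, TLX2 at 4.39 ± 1.48 and LINC01260 at 4.31 ± 1.50. COL5A1, a fibrillar collagen chain, at 5.20 ± 0.329 and the myosin gene MYH13 at 4.68 ± 0.685 were better determined in the same authors' deposited table. The largest falls there were those of MIR6783 at -4.99 ± 1.38, CD247 at -3.25 ± 0.995, CTXN1 at -3.18 ± 1.14, LOC101928163 at -3.16 ± 0.530, C2orf48 at -3.03 ± 0.223, FAM64A at -3.03 ± 0.280, EBF1 at -2.98 ± 1.18 and DIAPH3-AS1 at -2.95 ± 0.338. C2orf48 follows RRM2 on the same strand and DIAPH3-AS1 overlaps DIAPH3 on the other, and how the authors assigned reads of such pairs is not given in the sources used here. Among genes with an implied SE of at most 0.2, a limit set after the values had been seen, the authors' deposited table gave the largest rises to TP53INP1 at 3.27 ± 0.118, LINC01021 at 3.22 ± 0.158, GGT5 at 2.86 ± 0.181 and HIST1H2BK at 2.85 ± 0.112. ACTA2-AS1 at 2.62 ± 0.116, ACTA2 at 2.60 ± 0.0901, TGM5 at 2.39 ± 0.194 and CYFIP2 at 2.27 ± 0.0766 followed in the authors' deposited table, the first overlapping the second on the other strand. The falls of this kind in the authors' deposited table were led by PIF1 at -2.79 ± 0.184, PBK at -2.73 ± 0.105, ESPL1 at -2.70 ± 0.0839 and the fatty acid desaturase gene FADS2 at -2.69 ± 0.110, before CDK1, MYBL2, CKAP2L and SPC24.

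Listed transcriptional targets of p53 were higher with 1 exception. Of 54 target genes, 41 were listed and 40 of these were higher, with a median log2 fold change of 1.09, and the other 13 did not pass or were not tested. The cell cycle inhibitor gene CDKN1A was 3.76-fold higher (log2 fold change 1.91 ± 0.0579, adjusted p = 1.18e-235 in the authors' deposited table), and MDM2, whose product degrades p53, was 3.33-fold higher (1.74 ± 0.0631, adjusted p = 3.73e-164). TRIM22, at 2.05 ± 0.0604, and the stress-induced SESN1, at 2.07 ± 0.0679, had with CDKN1A the smallest adjusted p-values of the group in the authors' deposited table. PMAIP1, which encodes the pro-apoptotic protein NOXA, was that exception, lower at -0.83 ± 0.0992 in the authors' deposited table. Listed p53 targets were higher more often than the other genes of the table, 97.6% against 46.8% (two-sided Fisher's exact test, adjusted p = 1.04e-11 over the 19 lists tested). This test and those below compare directions among genes that had already passed, and they treat genes as independent.

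Genes of cell division fell together. All 40 G2/M and mitosis genes were listed and lower, with a median log2 fold change of -2.37, and all 45 genes of DNA replication and the G1/S transition were listed and lower, with a median of -1.94. The proliferation marker MKI67 was 5.74-fold lower (-2.52), TOP2A, which untangles chromosomes, 5.69-fold lower (-2.51) and the replicative helicase subunit MCM4 4.24-fold lower (-2.08) in the authors' deposited table, where these 3 genes have a p of 0 and thus no implied SE. The mitotic kinase gene CDK1 stood at -2.67 ± 0.0740, the ribonucleotide reductase subunit RRM2 at -2.52 ± 0.0671 and MCM10 at -2.55 ± 0.0731 in the authors' deposited table. Fisher's exact test against the other listed genes gave an adjusted p of 5.32e-11 for the mitosis genes and 3.80e-12 for the replication genes. That every member was listed was itself more than the table's share of 45.3% would give (one-sided hypergeometric test, a test added after the values had been seen, adjusted p = 1.97e-13 and 7.44e-15).

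**Figure D1:**
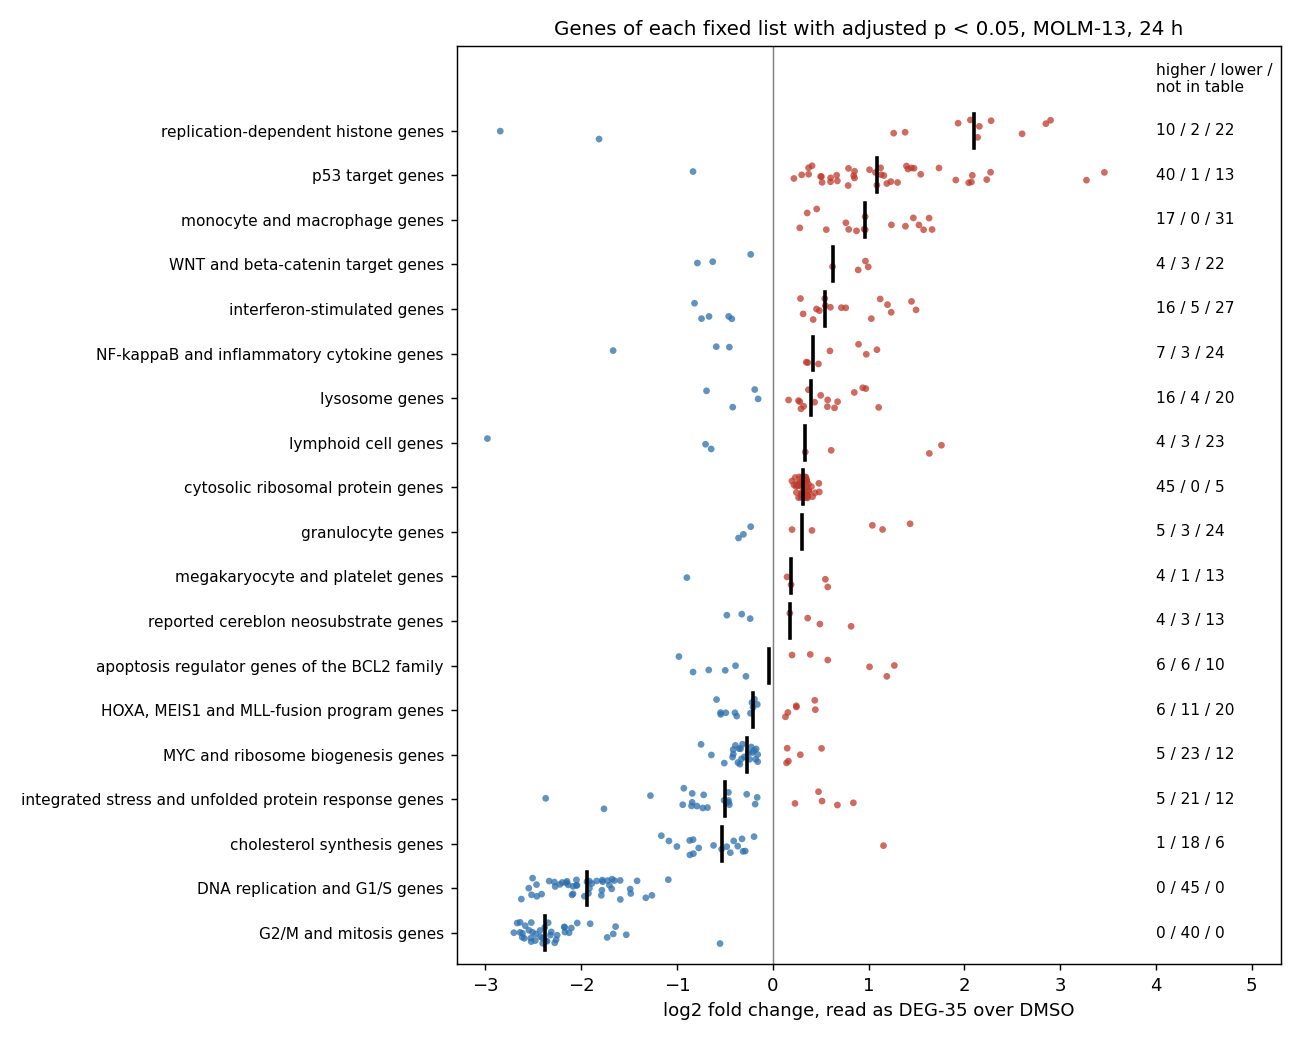
Each point is a listed gene of a gene list, placed by its log2 fold change in the authors' deposited table (read as DEG-35 over DMSO, red higher and blue lower), black bars are list medians, and the numbers at the right count higher, lower and unlisted members. The 40 mitosis and 45 replication genes all lie below 0, whereas 40 of 41 p53 targets and all 45 listed ribosomal protein genes lie above it.

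The listed cytosolic ribosomal protein genes rose slightly and uniformly. Of 50 genes, 45 were listed and all 45 were higher, with log2 fold changes between 0.20 and 0.49 and a median of 0.32 (Fisher's exact test, adjusted p = 3.14e-14), although 15 of them would turn lower if all log2 fold changes were shifted down by 0.3. RPL12 stood at 0.48 ± 0.0517, RPS19 at 0.49 ± 0.0601 and RPL4 at 0.42 ± 0.0528 in the authors' deposited table. Listed genes of the MYC program and of ribosome assembly mostly went the other way: 28 of 40 were listed, 23 of them lower, with a median of -0.27 (adjusted p = 0.00519). The polyamine synthesis enzyme gene ODC1, at -0.75 ± 0.0617, the rRNA processing gene UTP20, at -0.64 ± 0.0634, and the chaperonin gene HSPE1, at -0.51 ± 0.0618, fell in the authors' deposited table, and NOB1, which acts in small-subunit maturation, rose by 0.51 ± 0.0679. The call for this list was lost with all log2 fold changes shifted up by 0.3 (adjusted p = 0.766).

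Monocyte and macrophage genes that changed were all higher. Of 48 genes 17 were listed, 17 of them higher, with a median log2 fold change of 0.96 (Fisher's exact test, adjusted p = 1.03e-05). At 35.4%, the share of the list that was listed lay below the 45.3% of all tested genes. The integrin gene ITGAM (CD11b) was 2.77-fold higher (1.47 ± 0.0956), the inhibitory receptor gene LILRB4 2.36-fold higher (1.24 ± 0.0820) and the NADPH oxidase subunit NCF1 3.10-fold higher (1.63 ± 0.127) in the authors' deposited table, the last with near-identical copies that can share its reads. CD14, S100A8 and S100A9 were among the 31 members not listed. Granulocyte genes showed no common direction: 8 of 32 were listed, 5 higher and 3 lower (adjusted p = 0.618). The growth factor receptor gene CSF3R stood at 1.15 ± 0.0849, the protease gene CTSG at 0.41 ± 0.0568, BPI at 1.04 ± 0.155 and the repressor gene GFI1 at -0.31 ± 0.0614 in the authors' deposited table.

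Listed genes of the MLL-fusion program showed no common direction. Of 37 HOXA, MEIS1 and MLL-fusion program genes 17 were listed, 6 higher and 11 lower, with a median of -0.21 and no difference in direction from the rest of the table (Fisher's exact test, adjusted p = 0.618). HOXA10 fell by 0.54 ± 0.0675 and HOXA11 by 0.59 ± 0.0835 on the log2 scale, whereas the demethylase-family gene JMJD1C rose by 0.44 ± 0.0618 in the authors' deposited table. In the 17-gene LSC17 stemness score 4 members were listed, too few to test, with DNMT3B at -0.62 ± 0.0802, DPYSL3 at -0.52 ± 0.154, LAPTM4B at -0.14 ± 0.0575 and CDK6 at 0.16 ± 0.0640 in the authors' deposited table. Markers of other blood lineages were counted in the same way. Of 25 erythroid genes EPOR was the 1 listed, at -0.60 ± 0.136 in the authors' deposited table. Of 18 megakaryocyte and platelet genes 5 were listed, 4 of them higher (adjusted p = 0.302), with NFE2 at 0.55 ± 0.0713, GP1BA at 0.57 ± 0.183, PLEK at 0.19 ± 0.0694 and GP1BB at -0.90 ± 0.324 in the authors' deposited table. Of 30 lymphoid genes 7 were listed, 4 higher and 3 lower (adjusted p = 0.753), among them IL7R at 1.76 ± 0.122, CD4 at 0.61 ± 0.0561 and PAX5 at -0.70 ± 0.0727 in the authors' deposited table.

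Interferon-stimulated genes that changed were more often higher. Of 48 genes 21 were listed, 16 higher and 5 lower, with a median log2 fold change of 0.54 (Fisher's exact test, adjusted p = 0.0156, but 0.345 with all log2 fold changes shifted up by 0.3). The share of the list that was listed, 43.8%, did not exceed the 45.3% of all tested genes. IFIT1, ISG15, MX1 and OAS1 were among the 27 members not listed. The guanylate-binding protein gene GBP2 at 1.45 ± 0.118 and the transcription factor genes STAT2 at 0.76 ± 0.0696 and IRF1 at 0.72 ± 0.0731 had the smallest adjusted p-values of the list, and HERC5 fell by 0.74 ± 0.134 in the authors' deposited table. Of 34 NF-κB and inflammatory cytokine genes 10 were listed, 7 higher and 3 lower (adjusted p = 0.302), with CCL5 at 0.60 ± 0.0818, OSM at 1.09 ± 0.157 and SOD2 at -0.45 ± 0.0680 in the authors' deposited table. All 3 listed MHC class II presentation genes, of 18, were higher in the authors' deposited table, with the invariant chain gene CD74 at 1.03 ± 0.0696, CTSS at 0.43 ± 0.0760 and HLA-DQB1 at 1.28 ± 0.407, and were too few to test. Listed lysosome genes rose more often than they fell: 20 of 40 were listed, 16 higher and 4 lower, with a median of 0.40 (adjusted p = 0.00767, but 0.0629 with all log2 fold changes shifted down by 0.3). The acid ceramidase gene ASAH1 stood at 0.94 ± 0.0690, the saposin precursor gene PSAP at 0.68 ± 0.0555 and the glucuronidase gene GUSB at -0.69 ± 0.0763 in the authors' deposited table.

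Listed stress response and sterol genes were mostly lower. Of 38 genes of the integrated stress and unfolded protein responses 26 were listed, 21 lower and 5 higher, with a median log2 fold change of -0.50 (Fisher's exact test, adjusted p = 0.0105). The serine synthesis genes PHGDH, 3.39-fold lower (-1.76 ± 0.0746), and PSAT1, 1.92-fold lower (-0.94 ± 0.0617), fell in the authors' deposited table, and DDIT4, an inhibitor of mTORC1 signalling, was 1.79-fold higher (0.84 ± 0.0597). Of 25 cholesterol synthesis genes 19 were listed, 18 of them lower, with a median of -0.53 (adjusted p = 3.52e-04). INSIG1, a sterol-responsive regulator, stood at -1.16 ± 0.0708 and ACAT2 at -1.08 ± 0.0694 in the authors' deposited table, where TM7SF2 alone was higher, at 1.16 ± 0.162.

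Listed replication-dependent histone genes were mostly higher. Of 34 genes 12 were listed, 10 higher and 2 lower, with a median log2 fold change of 2.10 (Fisher's exact test, adjusted p = 0.0297, but 0.301 with all log2 fold changes shifted up by 0.3). The share of the list that was listed, 35.3%, lay below the 45.3% of all tested genes. The values are per gene, come from mRNA libraries and do not tell which forms of its transcripts were measured. No rise of total histone transcripts can therefore be read from them. HIST1H2BK at 2.85 ± 0.112, HIST1H2BD at 2.60 ± 0.308 and HIST1H2AC at 2.90 ± 0.410 rose in the authors' deposited table, and HIST2H2AC was lower at -2.84 ± 1.03. Histone genes have near-identical copies, so the assignment of their reads is uncertain, and 1 of the 12 had an implied SE of at most 0.2. Among genes with a larger implied SE, 9 of 11 histone genes were higher, 81.8% against 70.1% of all such genes, a comparison in which the call was lost (Fisher's exact test, adjusted p = 0.521).

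Other lists showed no common direction. Of 22 BCL2-family genes 12 were listed, 6 higher and 6 lower (Fisher's exact test, adjusted p = 1), with the pro-apoptotic BAX at 1.19 ± 0.0838 and BNIP3 at -0.98 ± 0.0995 in the authors' deposited table. Of 29 genes in the list of WNT and beta-catenin targets 7 were listed, 4 higher and 3 lower (adjusted p = 0.753). The adhesion receptor gene CD44 stood at 0.62 ± 0.0675, CCND1 at 0.89 ± 0.151 and ZNRF3 at -0.79 ± 0.113 in the authors' deposited table. That list also holds pathway components, among the listed members CTNNB1 (lower) and PORCN (higher). AXIN2, LEF1, TCF7 and NKD1 were not listed, so the count does not measure the activity of the pathway. The 20 genes of reported cereblon neosubstrates, with cereblon itself, had 7 listed members, 4 higher and 3 lower (adjusted p = 0.753), and ZNF276 at 0.49 ± 0.0863 followed IKZF2 in adjusted p in the authors' deposited table. None of the 15 mitochondrially encoded genes was listed, so they did not pass or were not tested under these symbols, and no change or lack of change can be read from this. Adjusted over the list alone, with unlisted members counted as tests that did not pass, no list could gain a member, as the p-values of unlisted genes are unknown. As many members passed as over all genes in every list but 2, the LSC17 score (2 in place of 4) and the lymphoid genes (6 in place of 7). For lists with a listed share above the 45.3% of all tested genes this was so by construction, so it is no separate support for them.

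**Figure D2:**
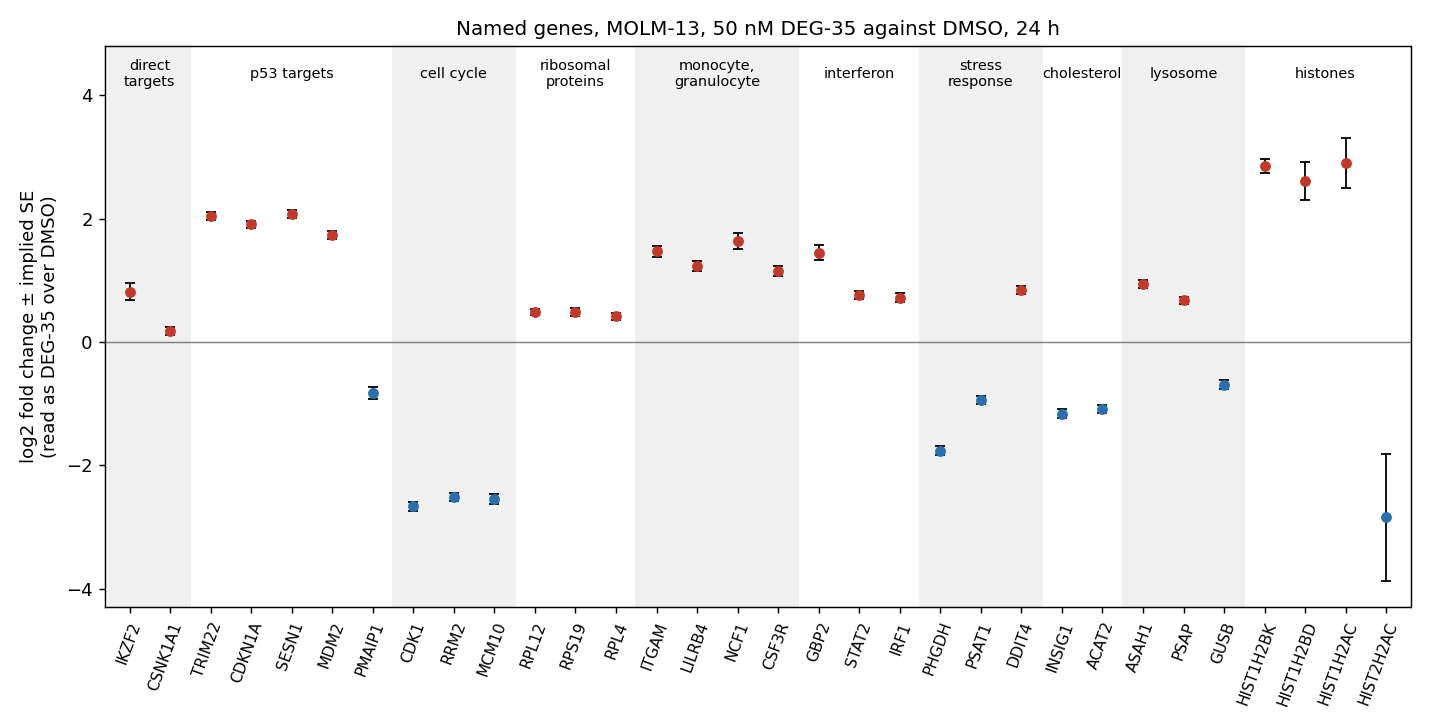
Points are log2 fold changes of selected named genes in the authors' deposited table (vertical axis, read as DEG-35 over DMSO), bars are ± 1 implied standard error, and shading separates the gene lists. CDKN1A at 1.91 and MDM2 at 1.74 lie far above 0, CDK1 at -2.67 far below it, and HIST2H2AC carries the widest error of the genes plotted, 1.03.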

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

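The alternatives with Bonferroni adjustment over 15064 tests, an implied SE limit either way and shifted fold changes, and all those for lists except leaving out shared members, were chosen after the data were seen. The counts of changed genes stayed within 1.5 times 6831 at an adjusted p of 0.01 (5540 genes) and an implied SE of at most 0.2 (5957, with the 3 genes that have a p of 0 and no implied SE kept). They fell to 1251 genes (637 higher, 614 lower) with an absolute log2 fold change of at least 1, to 3328 (1428 higher, 1900 lower) with Bonferroni adjustment over the table and to 3154 (1347 higher, 1807 lower) over 15064 tests, by construction, as these settings are stricter. Benjamini-Hochberg adjustment over the table alone returns all 6831 genes by construction. Of 104 named genes, 96 passed at an adjusted p of 0.01, 59 with the minimum change and 84 under each Bonferroni adjustment. Most of them had been chosen for a small adjusted p or a large change, so these counts partly follow from the choice. Lists kept their side of the threshold without shared members, with exact symbols, at an adjusted p of 0.01 (18 lists testable), with the minimum change (6 testable) and with an implied SE of at most 0.2 (17 testable), and lists with fewer than 5 members there gave no value. A shift of all log2 fold changes by 0.3 changed 4 calls: upwards, 53.6% of MYC and ribosome biogenesis genes (adjusted p = 0.766), 76.2% of interferon-stimulated genes (0.345) and 83.3% of histone genes (0.301) were higher and no longer passed, and downwards 60% of lysosome genes (0.0629). The cause is the shift, which moves the other genes of the table as well. The set of listed genes was held fixed, so these calls may differ from those that other scaling factors would give. Among genes with an implied SE above 0.2, 81.8% of histone genes were higher against 70.1% of all such genes, and the call was lost (0.521), and no other list was testable. No paired analysis was possible because the table holds no per-library values. For the same reason leaving out libraries, the replicate block, splits of the samples, other tools, size factors or pseudocounts, level filters and preset or estimated correlations were not run, and an adjusted p of 0.1 lies outside the table. Depth is unknown, so which unlisted genes were too thinly covered to pass cannot be said, and folds of 41 genes with an absolute log2 change of at least 3 rest on a median implied SE of 0.801.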

Other observations

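All tests in this part were chosen after the fold changes had been seen. Genes were grouped by the letters that open their symbols, and the 98 groups with at least 8 listed genes were compared with the table by Fisher's exact test. Nucleoporin genes (NUP), which build the nuclear pore, were lower in all 18 listed cases, with a median log2 fold change of -0.62 (adjusted p = 2.83e-04), and 1 would turn higher with all values shifted up by 0.3. NUP107 stood at -1.08 ± 0.0680 and NUP210 at -0.83 ± 0.0698 in the authors' deposited table. All 9 listed LSM genes, most of them subunits of RNA-binding rings in splicing and mRNA decay, were lower (median -0.54, adjusted p = 0.0367), 4 of which that shift would turn higher. All 8 listed HAUS genes of the spindle augmin complex were lower (median -0.86), which missed the threshold (adjusted p = 0.0535). Of 19 genes whose symbols open with IL, mostly interleukins and their receptors, 16 were higher (median 0.76, adjusted p = 0.0198), with IL16 at 1.45 ± 0.147 and IL21R at 1.65 ± 0.128 in the authors' deposited table, and IL18R1 lower at -1.82 ± 0.193. Of 33 genes with CD symbols 25 were higher (median 0.67, adjusted p = 0.0156), CD38, a surface marker of blood cells, at 1.28 ± 0.139 in the authors' deposited table. Of 14 listed vacuolar sorting genes (VPS) 12 were higher (median 0.33, adjusted p = 0.0367), and 8 with all values shifted down by 0.3. All 12 listed PCDHGA genes were higher (median 0.83, adjusted p = 0.00193), but they share 3' exons and with them reads, so they may count as a single measurement, like the overlapping genes of which 77.5% of pairs changed in the same direction.

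A few further single genes were also chosen after their values had been seen. The p53-induced microRNA gene MIR34A stood at 3.77 ± 0.921, the MYC-neighbouring non-coding gene PVT1 at 1.41 ± 0.0861, and the nuclear RNAs MALAT1 at 1.20 ± 0.0676 and NEAT1 at 0.81 ± 0.0612 in the authors' deposited table. The receptor tyrosine kinase gene FLT3, a member of the MLL-fusion program list, stood at 0.44 ± 0.0656 in the same authors' deposited table.

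The uniform rise of ribosomal protein genes (45 of 45 listed, median log2 fold change 0.32) was set against 3 explanations. A scaling shift common to all genes should raise other abundant genes. However, 40 listed oxidative phosphorylation subunit genes had a median of -0.22 (-0.224, SD of the genes 0.251), with 8 of them higher. This argues against a shift as the whole cause only if these genes had no fall of their own, which was not tested. Unlisted subunit genes could not be included. A gain of short transcripts stays open: 1930 other listed protein-coding genes no longer than the longest ribosomal protein gene by median transcript length had a median of -0.22 (-0.223), but they went both ways (832 higher) and spread too widely (SD 0.802) to decide. A response shared by mRNAs with a 5' terminal oligopyrimidine motif, a class that also holds translation factor genes, may account for it: 19 of 22 listed non-ribosomal members were higher (86.4%, exact binomial p = 1.77e-04), VIM, SNHG1 and SNHG12 being lower. Reads from ribosomal protein pseudogenes were not tested and stay open, as does the effect of DEG-35 on this class, which rests here on listed genes alone.

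Adjacent listed genes tended to change in the same direction when close. Of overlapping pairs 77.5% were concordant (613 of 791), and 58.9% of pairs less than 10 kb apart (permutation p = 1e-04 for each, the smallest that 10000 shuffles can give). Pairs 10 to 100 kb apart reached 51.9% (permutation p = 0.0824), or 51.0% without pairs of the same family (permutation p = 0.271). Both lie below the upper end of the central 95% of shuffles. Reads counted to both of a pair of overlapping genes may contribute. Any cause that acts on close genes alone would also leave distant pairs at the shuffled level, so the distance comparison cannot tell these apart. Overlapping pairs on the same strand were concordant in 85.1% of cases and those on opposite strands in 74.6%. As shared reads would give, 26 overlapping pairs had log2 fold changes within 0.01 and implied SEs within 5% of each other, against 2 pairs 10 to 100 kb apart. An example is SCHIP1 at 1.77 and IQCJ-SCHIP1 at 1.78 in the authors' deposited table. Neighbours of the same gene family do not explain the whole concordance, as overlapping or close pairs with different symbol stems were concordant in 64.0% of cases (upper end of the central 95% of shuffles 52.7%). For close pairs that do not overlap, shared divergent promoters (head-to-head pairs, 63.3% concordant, permutation p = 2.00e-04) and reads running past the end of a gene (tandem or tail-to-tail pairs, 56.2%, permutation p = 0.00150) both remain possible, the tail-to-tail pairs alone at 55.3% (permutation p = 0.0625).

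Listed long non-coding RNA genes were higher in 64.7% of cases (176 of 272), against 45.6% of protein-coding genes. Part of this goes with precision, since protein-coding genes matched on the implied SE, which stands in for the unknown level, were higher in a median of 56.3% of 10000 draws, but the observed share lies above the central 95% of these draws, which ends at 61.8%. Reads from an overlapping protein-coding gene are argued against as the whole cause by the 66 that overlap none, of which 72.7% were higher (the central 95% of matched draws ends at 66.7%). A level effect that the implied SE does not capture, reads from unannotated transcripts and an effect of DEG-35 on these RNAs remain possible and were not tested.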
